A study of Micropterus salmoides with 4 samples.

How the data were processed

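Liver RNA of adult female largemouth bass (Micropterus salmoides) was labelled with Cy3 and hybridised to single-colour Agilent oligonucleotide arrays, 1 array per sample. The fish had eaten pellets containing 17alpha-ethinylestradiol (EE2), a synthetic estrogen, at 0.2 mg per kg of feed on 5 days a week for 60 days, per the labels. The series' design text repeats this feed concentration but also gives a daily amount of EE2 per fish that is far too large to follow from it, so the dose each fish took in is uncertain. All 4 samples belong to this group and carry replicate numbers 1 to 4. Liver of control-fed fish was not analysed here, so no effect of EE2 was estimated. The labels do not say that each array holds a separate fish, so the spread between arrays may be partly technical.

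The deposited scanner tables hold spot intensities on a linear scale. Per the file headers, the authors extracted them with Agilent Feature Extraction 10.1.1.1, with extended dynamic range scanning, background subtraction with spatial detrending, multiplicative detrending and surrogate values for dim spots. The headers set a multiplicative error of 10% of the signal for each feature. The authors' deposited value table holds log2 values of 15088 probes. Comparison with the scanner tables showed each of its columns to be the log2 processed intensity of an array minus a constant, to within 1e-05, which fixes its scale. The column medians were 0, 1.5e-06, 0 and 0 for replicates 1 to 4, so the columns were centred on their medians, and a higher value means a brighter spot. All 120 probes absent from the table had been marked non-uniform by the scanner software on 2 or more arrays. The columns named for replicates 2 and 3 matched each other's scanner tables. The assignment of scanner tables to samples in the series record was used throughout, and the value table served only as an alternative.

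Each array carried 15744 features, of which 536 were controls and 15208 were gene probes 60 bases long. The gene probes were named by 15006 assembled contigs or sequence records, 202 of them with 2 probes. The deposited files give no gene symbol or description for any probe, since every description field read "Unknown". Of 29 sequence accessions used as names, 0 matched the reference gene table (assembly ASM1485139v1, 37622 genes). No probe was therefore given a gene name. The gene lists chosen before the data were examined could not be applied, and the tests of whether a list varied more than other genes or moved together were not run. Probes are given by their IDs. The rule for this case, set before the data were examined, names the 2 probes with the largest SD between arrays and the 2 with the smallest among those well above background on all 4 arrays and saturated on none.

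The value used for each probe was the log2 of the processed intensity minus the 75th percentile of that array's gene probes. A probe counted as detected when the software called it well above background on all 4 arrays. Control features were left out. For every measure of spread, probes marked non-uniform on any array were left out too, which removed 231 of the detected probes and left 7355 probes of 7307 contigs. No gene probe was marked as a population outlier or saturated. Where a contig had 2 probes, the brighter represented it in counts of contigs and in the principal component analysis.

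The measures were the SD of each probe over the 4 arrays, the number of contigs whose range over the arrays was 4-fold or more, the ratio of each probe's SD to the root mean square of its scanner error on the log2 scale, and the share of the variance around contig means on the leading principal component. The last was set beside 100 draws in which values were shuffled within contigs. Technical error within an array was also taken from sequences printed under 2 probe IDs. All 4 arrays lay on 1 slide and were scanned in 1 session, so a slide effect could not be estimated. No 2 scanner tables held the same values, and the SD of the difference between 2 arrays ranged from 0.49 to 1.14 on the log2 scale. Whether any 2 arrays carried RNA of the same fish was not tested. The number of arrays limits the precision of every SD.

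Alternatives were quantile normalization, the median in place of the 75th percentile, normexp background correction with an offset of 50, the deposited value table, other filters on dim or saturated probes, other size limits, the mean of a contig's probes, and each array left out in turn. Scaling on the Agilent E1A spike-in probes, removal of a quadratic trend on probe GC content and other treatment of non-uniform features were added after the data had been seen. The calculation was tested on simulated values of 7586 probes, 200 of them changed on 1 array. Every probe was given the same independent noise with an SD of 0.25, less than the median SD of 0.40 between the real arrays. The calculation returned a median SD of 0.23 against an expected 0.22. It counted a 4-fold or larger range for 0% of the probes changed 2-fold, 70% of those changed 4-fold and 100% of those changed 16-fold. Among the unchanged probes the share was 0%. These shares hold for that noise only, and the 0% does not carry over to the real counts. Normexp was run with limma 3.58.1 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88.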

Results

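Transcripts of 15006 assembled contigs and sequence records were measured in the liver of adult female largemouth bass after 60 days on a diet labelled as containing 0.2 mg of EE2 per kg of feed. The study asked which gene pathways of the liver respond to such an exposure. Only EE2-fed fish were analysed here, 4 arrays in 1 group, so the values describe liver RNA of exposed females and how much the arrays differed from one another, and no change caused by EE2 is given. The 75th percentile of the processed signal over gene probes was 317 on replicate 1, 441 on replicate 2, 320 on replicate 3 and 348 on replicate 4.

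Of the 15208 gene probes, 7586 were well above background on all 4 arrays, which is 49.9%. A further 4601 probes were well above background on none of them, and 3021 on 1 to 3. The number per array was 7957 on replicate 1, 9893 on replicate 2, 8348 on replicate 3 and 9758 on replicate 4. Replicate 2 was the only array to detect 645 probes, and replicate 4 was the only array to detect 443. The corresponding numbers were 85 for replicate 1 and 30 for replicate 3. The mean log2 signal of the negative controls was 3.37, 2.65, 3.13 and 2.45 on replicates 1 to 4.

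The spread between arrays was modest for most detected transcripts. The median SD over the 4 arrays was 0.40 on the log2 scale, with an interquartile range of 0.26 to 0.62, which corresponds to a factor of 1.32 for 1 SD at the median. The median ratio of the SD to the scanner's error was 2.49, with a median error of 0.15, and it was 1.30 with no filter on dim probes. The unfiltered ratio includes probes whose values were surrogates set by the software. The SD was larger than the error for 90.1% of the 7355 probes. The scanner's error builds on the 10% of the signal preset in the software, so it is largely a setting and not measured from repeated spots. A second estimate of error within an array, measured from the spots, came from 34 sequences that were printed at 2 spots and passed the filters. Within an array the difference between their 2 spots had an SD of 0.18, which corresponds to an SD of 0.12 for a single spot, whereas the median SD of these sequences between arrays was 0.55. Neither error includes labelling or hybridisation, so the share of the spread that is technical is not known. The median SD fell from 0.40 to 0.24 without replicate 2, and the median ratio to the error fell to 1.46.

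**Figure D1:**
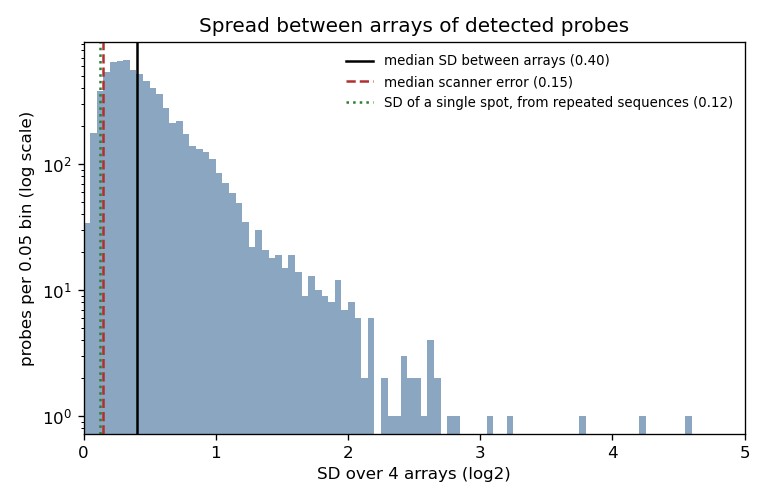
Histogram of the SD over the 4 arrays (x axis, log2 units) of 7355 detected probes, with the number of probes per bin on a log scale (y axis). Lines mark the median SD between arrays of 0.40, the median scanner error of 0.15 and the SD of 0.12 of a single spot, estimated from sequences printed at 2 spots, and the SD of most probes lies to the right of both error lines.

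A smaller set of transcripts differed strongly between the 4 arrays. Of 7307 contigs, 808 (11.1%) had a 4-fold or larger range over the 4 arrays, 85 had a range of at least 16-fold and 6 had a range of at least 64-fold. Replicate 2 was the lowest array for 459 of the 808 contigs and the highest for 280. Replicate 4 was highest for 254 and lowest for 171, replicate 3 highest for 195 and lowest for 115, and replicate 1 highest for 79 and lowest for 63. Directions here are relative to the 75th percentile and were not counted under spike-in scaling. On the log2 scale, the 75th percentile minus the spike-in mean was -2.22 on replicate 2. It was -2.81, -3.12 and -3.33 on replicates 1, 3 and 4. Spike-in scaling would therefore raise replicate 2 relative to each other array. Replicate 2 alone lay at least 4-fold above every other array for 70 contigs and at least 4-fold below every other array for 134. No other array did so for more than 12 contigs in either direction. Detection on all 4 arrays was required, which left out 645 probes detected on replicate 2 alone and 50 detected on all but replicate 2. These counts therefore do not tell whether replicate 2 lay above or below the other arrays more often. The count of 808 was 485 with normexp background correction, 1505 with scaling on the spike-in probes and 1920 with no filter on dim probes. The unfiltered count includes surrogate values set by the software, which 1842 gene probes held on all 4 arrays. Without replicate 2 the count of contigs with a 4-fold or larger range was 168, whereas it was 749, 682 and 610 without replicates 1, 3 and 4.

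**Figure D2:**
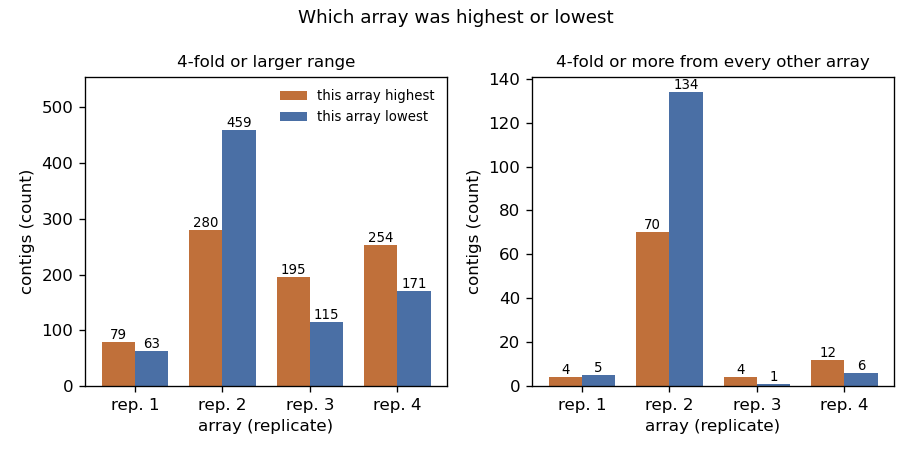
Number of contigs (y axis) for which each array (x axis, replicates 1 to 4) was the highest or the lowest. The left panel covers the 808 contigs with a 4-fold or larger range and the right panel those in which the array lay at least 4-fold from every other array, where replicate 2 accounts for 70 contigs above and 134 below. Only probes detected on all 4 arrays are counted.

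The 2 probes with the largest spread were highest in replicates 1 and 3. Probe UF_Msa_AF_103975, designed on contig18132 with the sequence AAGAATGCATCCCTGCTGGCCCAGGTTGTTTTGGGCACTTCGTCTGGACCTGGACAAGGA, had a log2 value relative to the array's 75th percentile of 3.06 ± 4.59 (SD, n = 4). Its value was 7.67 on replicate 1 and 6.29 on replicate 3, but -1.44 on replicate 2 and -0.30 on replicate 4. The range was 553-fold, against a scanner error of 0.15 on the log2 scale. Probe UF_Msa_AF_106235, designed on contig07203 with the sequence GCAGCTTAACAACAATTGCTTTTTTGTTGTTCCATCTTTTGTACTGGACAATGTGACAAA, had a value of 4.12 ± 4.24 (SD, n = 4). It stood at 7.83 on replicate 1, 7.23 on replicate 3, 2.58 on replicate 2 and -1.17 on replicate 4, a range of 513-fold. Its SD was 2.87 without replicate 4, which carried the lowest value. The files do not pair these probes with gene names, and no genome was used here, so their positions are not given.

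The 2 probes with the smallest spread were level over the 4 arrays to within 1.03-fold. Probe UF_Msa_AF_104065, on contig20479 with the sequence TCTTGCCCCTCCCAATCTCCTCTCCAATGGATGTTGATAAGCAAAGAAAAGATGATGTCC, had a log2 value of -0.16 ± 0.016 (SD, n = 4). Probe UF_Msa_AF_102614, on contig26490 with the sequence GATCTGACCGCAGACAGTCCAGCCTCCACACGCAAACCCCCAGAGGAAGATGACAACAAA, had a value of -2.38 ± 0.019 (SD, n = 4). These SDs lay below the scanner error of 0.15 and 0.21, and the probes were picked as the lowest of 7355. Their level course is relative to the 75th percentile, since scaling on the spike-in probes raised their SDs to 0.47 and 0.50.

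**Figure D3:**
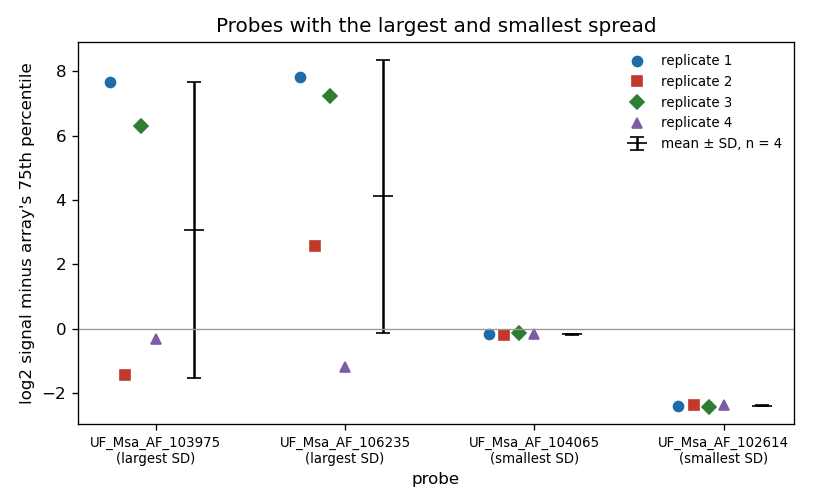
Log2 signal minus the array's 75th percentile (y axis) of the 2 probes with the largest and the 2 with the smallest SD (x axis). Coloured symbols are the 4 arrays and the black bars are the mean ± SD (n = 4). Replicates 1 and 3 lie between 6.29 and 7.83 on the first 2 probes, above replicates 2 and 4.

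The 4 arrays did not contribute evenly to the spread. The leading principal component carried 72.3% of the variance around the contig means, and the next carried 18.9%. Shuffling the values within contigs gave at most 36.5% for the leading component in 100 draws. Its weight was 0.85 for replicate 2, against -0.14, -0.33 and -0.38 for replicates 1, 3 and 4. The SD of an array's deviations from the probe means was 0.76 on replicate 2, compared with 0.36, 0.40 and 0.48 on replicates 1, 3 and 4. Across probes, which are not independent replicates, replicate 2 correlated with the other arrays at r of 0.881 to 0.915, whereas the other pairs gave 0.961 to 0.979. The array called replicate 2 here is the one whose scanner table the series record assigns to that sample. In the deposited value table the same values stand in the column named for replicate 3.

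The brightest transcripts are largely missing from the measures of spread. Of the 153 probes in the brightest 1% by mean signal, 151 were marked non-uniform on at least 1 array. With such features kept, the median SD was 0.40 and 830 contigs had a 4-fold or larger range.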

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

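The tests on repeated sequences and on GC content, and the use of the spike-in probes, were chosen after the results had been seen, while the test of scaling was planned.

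Replicate 2 stood apart from the other arrays in the number of contigs at least 4-fold above every other array, which was 70 against 4, 4 and 12. The gap to the nearest array was 0.879 of the whole range, above Dixon's 95% critical value for 4 samples. The corresponding number below every other array was 134 against 5, 1 and 6, with a gap of 0.962 of the range. These were the 2 of 19 sets of per-array values past that limit, and chance gives about 1 in 20. Both are counts in the tails of the same deviations, so they are not independent. The SD of the deviations, 0.76 on replicate 2 against 0.36, 0.40 and 0.48, was not past that limit. Neither was the mean correlation with the other arrays, 0.897 on replicate 2 against 0.952, 0.949 and 0.939. Measurement noise at single spots is argued against for the 34 sequences printed at 2 spots, where the deviations of replicate 2 correlated between spots at r = 0.996. The other arrays gave r of 0.954 to 0.995. These sequences varied more between arrays than the whole set, with a median SD of 0.55 against 0.40. Scaling that differs with intensity is argued against as the whole cause: after quantile normalization the SD of replicate 2's deviations was still 1.56 times the highest of the other arrays, against 1.58 before. A trend on probe GC content is argued against in the same way, with a ratio of 1.57 after its removal. RNA quality, the mix of tissue in the piece of liver, the hybridisation of that array, a wrong sample label and a real difference between fish stay open. They were not tested for replicate 2, and neither was any biological explanation.

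The E1A probes of the array, which report RNA added in a fixed amount during labelling in Agilent's standard protocol, were not part of the comparisons. Of 10 such probes, 7 were above the negative controls on all 4 arrays. The 75th percentile of the gene probes relative to the mean of 5 of them was -2.81, -2.22, -3.12 and -3.33 on the log2 scale on replicates 1 to 4, a range of 2.16-fold. The arrays therefore differed in gene signal per spike-in signal, with replicate 2 the highest.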

How the results depend on the processing

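Values without a test were called changed when they moved by more than the SD of the 4 values with 1 array left out, and counts when they moved by more than 1.5 times. By this rule 55 of 71 alternative values of the main measures did not change. They include values that could not change, as no probe was saturated, and values with 1 array left out, which themselves set the limit. That limit was wide: a fall of the median ratio to the scanner's error from 2.49 to 1.95 with normexp counted as no change. The 55 of 71 is therefore not a measure of robustness. Normexp background correction lowered the median SD from 0.40 to 0.31 and the contigs with a 4-fold or larger range from 808 to 485. With no filter on dim probes, the median SD was 0.51, the count 1920, the median ratio to the scanner's error 1.30 and the share on the leading component 58.6%. These unfiltered figures include surrogate values, which the software set and which 1842 gene probes held on all 4 arrays. They are therefore not measures of transcripts alone. Spike-in scaling, chosen after seeing the data, gave a median SD of 0.56, a count of 1505 and a ratio of 3.51. Requiring a 2-fold range gave 3199 contigs and an 8-fold range 225, as fewer or more pass by construction. Leaving out each array in turn gave 7599 to 8132 detected probes, or 7636 without replicate 2, a median SD of 0.24 to 0.43, a count of 168 to 749, a ratio of 1.46 to 2.68 and a leading share of 68.2% to 86.3%. The lowest of each of these 4 measures of spread came without replicate 2. A count of contigs over 3 arrays is lower by construction, but it stayed at 610 or more without any other array. The number of detected probes is higher by construction, since fewer arrays must pass. The lowest value the leading share can take is also higher, since 3 arrays leave only 2 components. These shares therefore cannot be set against the 72.3% over 4 arrays. Apart from these constructions the cause was not tested. The 2 probes with the largest SD stayed between 4.04 and 4.63 under other scalings and background corrections. The smallest SDs were less stable: that of UF_Msa_AF_104065 ranged from 0.0083 without replicate 3 to 0.055 with the value table and 0.47 with spike-in scaling, and that of UF_Msa_AF_102614 from 0.011 without replicate 3 to 0.087 with normexp and 0.50 with spike-in scaling. The exchanged columns of the value table change no SD or range. Leaving out saturated probes changed nothing, since there were none. The slide as a block and random gene lists were not run, as there was 1 slide and no probe had a gene name. Dim probes limit the set: 4601 were well above background on no array.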

Other observations

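The test of exchanged columns and the comparisons of probe series and orientations were chosen after the data had been seen, while those of the 4-fold ranges were written before their results.

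Contigs with a 4-fold or larger range were examined for spot-level measurement noise. Among the 34 sequences printed at 2 spots, 7 had such a range at the first spot, and 100% of them had a range of 2-fold or more at the second, all 7 of them 4-fold or more. This argues against noise at single spots for these sequences, and says nothing about errors that a whole array shares. The probe with the third largest SD, UF_Msa_AF_108253 on contig05019, chosen after its values were seen, has the sequence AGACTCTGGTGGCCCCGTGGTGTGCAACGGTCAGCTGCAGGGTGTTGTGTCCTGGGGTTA. Its log2 value relative to the 75th percentile was 7.85, 2.21, 7.21 and 0.08 on replicates 1 to 4, the same arrays being high as for the 2 probes with larger SDs. One reading frame holds a motif typical of the active site of trypsin-like serine proteases. A hypothesis is that tissue rich in trypsin-like proteases in part of the pieces may have added to these ranges. Only 2 other contigs in the set carried the motif or its histidine counterpart, 1 on the probe strand and 1 on the opposite strand. Of these, 0 had a 4-fold range (Fisher's exact p = 1, one-sided). That is too few to decide, and the motif alone does not tell which tissue a transcript came from.

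In the deposited value table, the columns named for replicates 2 and 3 may have been exchanged. Each minus the log2 signal of the other's scanner table was constant, with an SD of at most 2.1e-06, whereas against its own scanner table the SD was 1.09. The columns for replicates 1 and 4 matched their own scanner tables. Whether the table or the assignment of scanner tables is in error is not decided by these values. The measures of spread do not depend on it, but the name of the array that stands apart does.

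Features marked non-uniform were concentrated among bright spots. Of 239 gene probes marked on at least 1 array, 230 lay above the 95th percentile of mean signal, and 52 were marked on all 4 arrays.

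Probe IDs fall into 3 series, AF, CF and AD, whose meaning the files do not state. On all 4 arrays, detection covered 60.9% of 7393 AF probes (95% Wilson interval 59.8% to 62.0%) and 38.4% of 7421 CF probes (37.3% to 39.5%). Fisher's exact test, two-sided, gave p = 1.3e-166 and 7.8e-166 after Benjamini-Hochberg adjustment over 6 comparisons. Of 394 AD probes, 60.4% were detected, with an adjusted p of 2.8e-17 against CF and 0.874 against AF. By orientation, 41.6% of CF probes without "rc" in the contig name and 34.9% of those with it were detected (adjusted p = 7.1e-09). The same comparison gave 61.5% and 60.0% in AF (adjusted p = 0.296) and 61.9% and 58.9% in AD (adjusted p = 0.728), so no difference was shown there. These intervals and tests are across probes, which are not independent, and cover 1 group of arrays. CF probes were less often well above background than AF probes on each of the 4 arrays. The AD series holds a probe in each orientation for 197 records, and 46 of these pairs shared 12 or more bases as reverse complements. For 85 of the 197 records both probes were detected on all 4 arrays, against 71.8 expected if the 2 were independent (Fisher's exact p = 1.1e-04, two-sided). For 68 records 1 probe was detected and for 44 neither was. Among the 46 overlapping pairs, both strands were detected for 22. Across the 47 records with both probes in the measures of spread, the deviations of replicate 2 correlated between the strands at r = 0.408, and those of the other arrays at 0.231 to 0.441.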
